A study of Mus musculus with 5 samples.

How the data were processed

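Drop-seq libraries of mouse kidney were analysed: cortex, outer medulla and inner medulla with 1 library each, and whole kidney with 2 libraries. Per the labels' protocols, kidneys were perfused with cold buffer, whole organs or microdissected parts were minced and digested with a protease that works in the cold, cells were fixed in methanol and frozen, and Drop-seq libraries were sequenced on an Illumina NextSeq 500. The submitters' processing notes name the mouse genome build mm9 and Seurat 2.3.1, with no role for either. The aligner, the annotation and any correction of barcodes or UMIs are not given in the sources used here. The labels do not say how many animals were used or whether the regions came from the same animals, so the 2 whole kidney libraries may or may not be separate animals. No genomic coordinates are given, since the deposited tables carry gene symbols only and the reference at hand is of another build.

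The values are counts: the deposited tables give whole-number UMI counts per gene symbol and barcode, and the values show no normalization. They list 11443 barcodes for cortex, 10895 for outer medulla, 4035 for inner medulla, 12648 for whole kidney 1 and 15051 for whole kidney 2, with totals of 3527638, 2715993, 869732, 2910597 and 4169677 UMIs. Each barcode had at least 50 genes, and 13751 to 14660 genes were listed per library (16934 in all). No mitochondrially encoded genes were listed (0 symbols), so a filter on the mitochondrial share could not act and RNA quality could not be read from it.

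Cells were barcodes with at least 200 detected genes (3072, 2428, 898, 2418 and 3305 in the order above). Doublets were looked for in each library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 5%. It marked 24 of 12121 cells (0.198%), which is too few for the caller to be taken as having worked, so doublets largely remain. The marked cells were removed, and an alternative removed the 5% of cells with the highest doublet scores in each library. The 12097 remaining cells were scaled to a common depth, log-transformed and reduced to 2000 variable genes and 30 principal components without integration of libraries, and a shared-neighbour graph of 15 neighbours was partitioned with leidenalg 0.10.2 at resolution 1.0. Each of the 16 clusters took the class with the highest mean log2 level of its markers over the median cluster, from 16 marker lists (161 of 168 genes listed) fixed before the data were examined, if at least 3 markers were detected in 10% of its cells. The erythroid list was left out of this choice and of the marker score of single cells, so no cell could be named erythroid. Every named cluster had at least as many markers of its own class as of any other among its 10 leading genes. The cluster scoring as immune was split once more, a choice made after seeing the data, and 273 of its 326 cells, which had under 3 macrophage markers, were left unnamed.

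For each class and library, UMIs were summed over cells and divided by the class total to give CPM. A class was compared in a library only with at least 30 cells and 20000 UMIs. With 1 library per region the regions have no replicates, so no test was run and no p-value is given. The sums carry exact Poisson intervals, ratios of sums exact conditional intervals and shares exact Clopper-Pearson intervals at 95%, and all cover counting error only. The log2 ratios are of CPM plus a pseudocount of 10, which understates changes of low genes, whereas folds and their intervals are plain ratios. Against 0 counts, a fold is a lower bound computed with 3 counts in the sum of that library. For a count of genes past a fixed size (100 CPM in the higher library and 1 on the log2 scale), the class sums set side by side were thinned to a common total, and the median over 20 thinnings is given beside the same count for whole kidney 2 over whole kidney 1 and beside 20 draws of both sums from a pooled profile. These counts describe sizes and are not counts of changed genes.

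The rule for named genes was fixed before the data were examined. Per comparison, it takes up to 12 genes in each direction with the largest log2 ratios among genes with at least 100 CPM and 30 UMIs in the higher library, a log2 ratio of at least 1 in size and a level of at least 0.5 times that of all other cells of that library, without mitochondrial, ribosomal protein and haemoglobin genes. To these it adds measured members (at least 20 CPM in either library) of fixed gene lists and the markers of the class. Of 22 lists, each was summarised by the median log2 ratio of its measured members and the percentile of that median among 10000 random lists matched on mean expression. Free RNA was followed with the proximal tubule markers, whose share in other classes was set against the share in barcodes with under 100 genes. Read this way, free RNA made up 16.0% of UMIs in principal cell-like cells of cortex, 11.7% in those of outer medulla and 3.35% in those of inner medulla (proximal markers 0.0554% of UMIs, against 1.04% in cortex), and 17.9% and 19.9% in thick ascending limb-like cells of cortex and outer medulla.

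The comparisons were tested on simulated data over 16934 genes with 200 genes changed. For principal cell-like cells of inner medulla against cortex, every gene raised 4-fold or 8-fold passed the size and level parts of the rule, 26.5% of those raised 2-fold did, and 21.2% of those lowered 4-fold did, since a gene must have 30 UMIs in the shallower cortex sum. In that simulation 103 of 2163 unchanged genes at 100 CPM or above also passed, so a gene with few UMIs in cortex is weak evidence by itself. For proximal tubule-like cells 0 of 1453 unchanged genes passed, and every 4-fold change did. Genes lowered in the other comparisons were passed less often than in proximal tubule-like cells. Of genes lowered 4-fold, 3.03% passed in principal cell-like cells of outer medulla, 9.09% in thick ascending limb-like and 33.3% in intercalated cell-like cells, where 61.8% of those raised 4-fold and 0% of those raised 2-fold passed. Of 3988 cells drawn from the class profiles, 97.5% returned to their class, but 3 of 89 drawn from the unnamed cells did. Simulated cells of a class and library differed by depth and counting noise alone, so this return does not show how well real cells were named. The simulated sums likewise left out variation between libraries of the same kind.

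For the regional signature, up to 50 genes per direction were taken from principal cell-like cells of inner medulla and cortex by the same rule, and whole kidney cells were thinned to 500 UMIs before scoring. Alternatives covered the cell filter, doublets, clustering, class assignment, scaling, pseudocount, level filter, summing against averaging over cells, depth of thinning and size of the signature. A level filter of 500 CPM, thinning to 200 UMIs, the removal of high doublet scores and the subtraction of a free RNA profile were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0.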

Results

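Kidneys of wild-type mice of the strain that the labels give as C56BL/6N were digested with a cold protease, fixed in methanol and profiled by Drop-seq, in which single cells share a droplet with a barcoded bead and each captured mRNA molecule carries a unique molecular identifier (UMI). The series holds 5 libraries: 1 each of microdissected cortex, outer medulla and inner medulla, and 2 of whole kidney. After a filter at 200 detected genes and removal of marked doublets, 3071 cells of cortex, 2418 of outer medulla, 896 of inner medulla, 2408 of whole kidney 1 and 3304 of whole kidney 2 remained. They carried 2557841, 1744389, 518070, 1826122 and 2882062 UMIs, with a median of 517 UMIs per cell in cortex, 466 in outer medulla, 439 in inner medulla, 481 in whole kidney 1 and 501.5 in whole kidney 2. With 1 library per region, no test between regions was run, since a spread could be had from the whole kidney libraries alone. Ranges in parentheses after shares are exact 95% binomial intervals, those after folds are exact 95% intervals of the ratio of the class sums, and both cover counting error only. The difference between the 2 whole kidney libraries is set beside the regional differences as the spread between libraries of the same kind. It is called the library spread below.

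The series title asks whether single-cell profiles carry position along the corticomedullary axis, and the make-up of each region's library was compared as a starting point. Proximal tubule-like cells, which reabsorb most of the filtrate, made up 75.3% (73.8 to 76.8) of cortex cells and 66.0% (64.1 to 67.9) of outer medulla cells, but 10.2% (8.26 to 12.3) of inner medulla cells. Principal cell-like cells, the water- and sodium-reabsorbing cells of the collecting duct, ran the other way, with 1.82% (1.38 to 2.36) in cortex, 6.70% (5.74 to 7.77) in outer medulla and 54.2% (50.9 to 57.5) in inner medulla. Thick ascending limb-like cells made up 2.15% (1.67 to 2.73), 9.55% (8.41 to 10.8) and 11.9% (9.89 to 14.2) of the cells of these libraries. Thin limb-like cells numbered 126 of 896 in inner medulla, or 14.1% (11.9 to 16.5), against 24 cells in outer medulla and 2 in cortex.

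Connecting tubule-like cells made up 6.41% (5.57 to 7.34) of cortex cells, 1.61% (1.15 to 2.20) of outer medulla cells and 0.112% (0.00283 to 0.620) of inner medulla cells. Distal convoluted tubule-like cells made up 6.48% (5.63 to 7.41), 4.51% (3.72 to 5.41) and 0.446% (0.122 to 1.14). Podocyte-like cells, the filtering epithelium of the glomerulus, numbered 24 in cortex and 15 in outer medulla, and 0 of 896 in inner medulla. The exact binomial interval of that inner medulla share reached up to 0.411%, and 3 counts of the total would be 0.335%. Intercalated cell-like cells, the acid-base cells of the collecting duct, held 2.31% (1.81 to 2.91) of cortex, 2.19% (1.65 to 2.86) of outer medulla and 4.46% (3.21 to 6.03) of inner medulla cells. Endothelial-like cells held 1.66% (1.24 to 2.18), 1.65% (1.18 to 2.25) and 3.79% (2.64 to 5.26). The whole kidney libraries resembled the cortex library in these shares, with proximal tubule-like cells at 76.6% (74.8 to 78.3) and 80.8% (79.5 to 82.2) and principal cell-like cells at 2.24% (1.69 to 2.92) and 1.85% (1.42 to 2.37). Microdissection, digestion and capture all set such shares, and the class of a cell was rebuilt here from marker genes. Several shares depended on that step. With the class taken from each cell's own marker score, the principal cell-like shares of cortex, outer medulla and inner medulla were 3.39%, 8.40% and 45.0%, the proximal tubule-like shares 49.4%, 38.6% and 5.13% and the thin limb-like shares 2.44%, 4.71% and 20.6%. Thick ascending limb-like shares were then 5.57%, 16.1% and 11.8%, so that outer medulla stood above inner medulla, and connecting tubule-like shares were 13.3% in cortex and 3.76% in outer medulla. With cells of at least 500 genes only, the principal cell-like share of inner medulla was 78.6%, no thin limb-like cells were named, thick ascending limb-like shares were 1.19%, 3.40% and 5.34%, the connecting tubule-like share of cortex was 3.69%, the intercalated cell-like share of outer medulla 0.972% and the endothelial-like share of inner medulla 1.46%, near that of cortex. Removal of the 5% highest doublet scores, added after seeing the data, gave a principal cell-like share of 2.88% in cortex and a connecting tubule-like share of 4.35%. In whole kidney 1 and 2, the principal cell-like shares were 3.44% and 2.48% with this removal and 4.36% and 3.12% with the marker score.

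**Figure D1:**
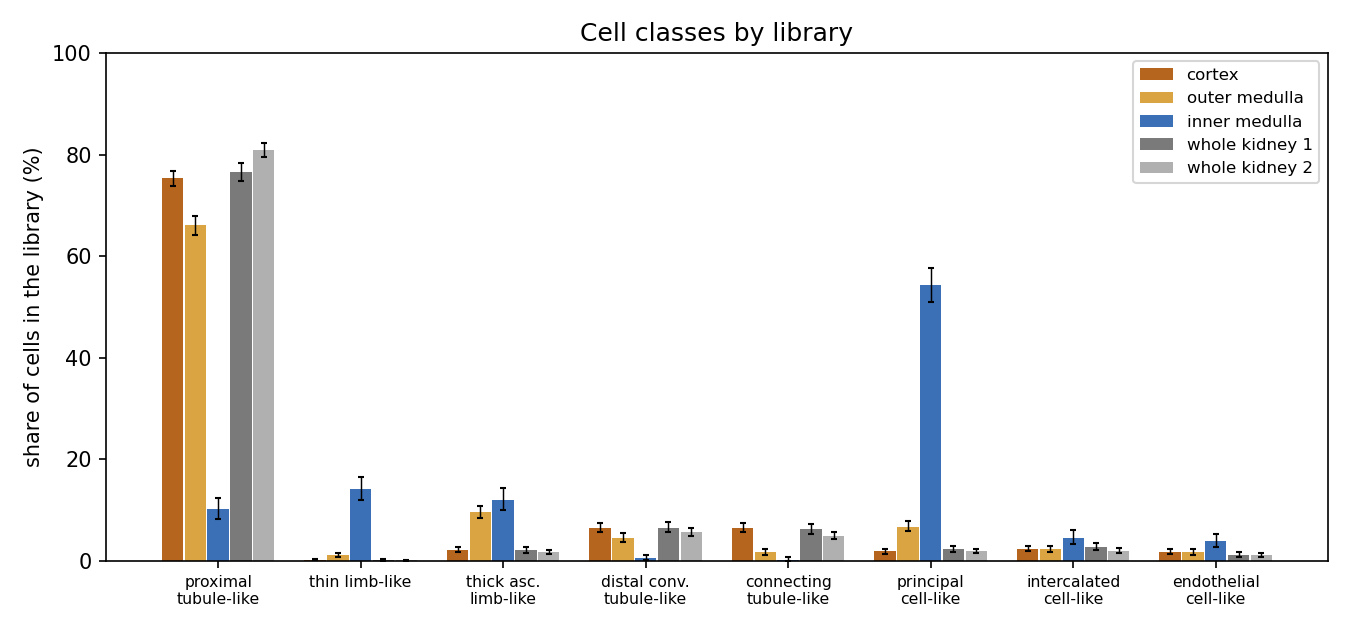
Share of cells (y axis, percent of the cells in a library) of 8 cell classes (x axis) in the 5 libraries (bar colours), with exact 95% binomial intervals as error bars. Proximal tubule-like cells stand at 75.3% in cortex and 10.2% in inner medulla, and principal cell-like cells stand at 54.2% in inner medulla.

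The collecting duct crosses all regions, so principal cell-like cells of inner medulla (486 cells, 305060 UMIs) were compared with those of cortex (56 cells, 40110 UMIs). Aqp2, the vasopressin-regulated water channel, was abundant in both, at 21937 CPM (UMIs scaled to a class total of 1e6) in inner medulla and 16156 CPM in cortex. The basolateral water channels went opposite ways: Aqp4 had 1081 UMIs (3544 CPM) against 5 UMIs, 28.4-fold higher in inner medulla (12.1 to 87.7), whereas Aqp3 stood at 1868 against 6258 CPM, 3.35-fold lower (2.88 to 3.89). The urea transporter gene Slc14a2 had 143 UMIs in inner medulla and 0 in cortex, at least 6.27-fold higher against a floor of 3 counts in the cortex sum. Cryab, a small heat shock protein gene, was 31.9-fold higher (17.8 to 64.0), at 8756 against 274 CPM, although barcodes with under 100 genes, read as background, held Cryab at 8585 CPM in the inner medulla library and 42.5 CPM in the cortex library. Hsd11b2, whose enzyme shields the mineralocorticoid receptor from glucocorticoids, was 17.1-fold lower (13.8 to 21.4), at 393 against 6731 CPM.

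Sodium and potassium transport genes of the collecting duct were mostly lower in inner medulla. Of 14 measured members, 11 were lower and 7 of them had counting intervals below equality, with a median log2 ratio of -1.63 and of -1.40 with zero-count genes at their bound, the 0.0 percentile of 10000 random lists matched on mean expression. All 3 subunits of the epithelial sodium channel were lower: Scnn1a with 4 against 7 UMIs (13.1 against 175 CPM), Scnn1b with 7 against 16 UMIs (22.9 against 399 CPM) and Scnn1g 15.2-fold (6.80 to 36.4). The potassium channel gene Kcnj1 had 3 UMIs in inner medulla and 27 in cortex, a ratio of 68.5 (21.1 to 353). Atp1b1, a subunit gene of the sodium pump, was 1.52-fold lower (1.30 to 1.77), while Fxyd4, a regulator of that pump, was 1.28-fold higher (1.12 to 1.47). The median of this list was -1.45 with TMM factors, with 10 of 14 lower, and -0.02 between the whole kidney libraries.

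Osmolyte and osmoprotective genes leaned upward, with 8 of 11 measured members higher and 5 of these with intervals above equality. Their median log2 ratio was 1.87, at percentile 100 of matched lists, or 0.66 with zero-count genes at their bound. Besides Cryab and Slc14a2, the heat shock gene Hspb1 had 172 UMIs against 0, at least 7.54-fold higher, and the kinase gene Sgk1 was 4.40-fold higher (2.10 to 11.1), although Sgk1 also differed between the whole kidney libraries by 3.04 on the log2 scale. The inositol transporter gene Slc5a3 had 36 UMIs against 1, with an interval that included equality, and the taurine transporter gene Slc6a6 went the other way, 5.32-fold lower (1.72 to 15.5). The water and urea transport list, which shares Slc14a2, had a median of 0.44, at the 88.3 percentile.

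The nuclear genes of oxidative phosphorylation were lower in inner medulla principal cell-like cells in 23 of 24 cases, 21 with intervals below equality. Their median log2 ratio was -1.14, at the 0.0 percentile, against 0.26 between the whole kidney libraries. Genes of proximal segments S1 and S2, from another cell type, moved the same way, with 7 of 7 lower and a median of -3.02. Free RNA was estimated at 3.35% of UMIs in these cells of inner medulla (proximal markers 0.0554% of UMIs, against 1.04% in cortex). With a free RNA profile subtracted, a step added after seeing the data, all 17 list medians outside proximal tubule-like cells stayed within their counting spread. The oxidative phosphorylation median was among them. Cox6c stood at 1147 against 3067 CPM, 2.67-fold lower (2.16 to 3.29), Cox4i1 was 2.25-fold lower (1.83 to 2.76) and Atp5b 2.23-fold lower (1.67 to 2.95). Ndufb8 was the exception, 1.48-fold higher (1.02 to 2.22). With TMM factors, whose log2 shift was -0.30 here and raised the ratios, the median was -0.85 and 21 of 24 members were lower. Of the cytoskeletal keratin and S100 genes, 10 of 13 were higher in value, 5 of them by interval, and 1 was lower by interval, with a median of 0.57 and of 0.29 with zero-count genes at their bound. Anxa2 was higher, with 190 UMIs against 5 (interval 2.10 to 15.6) and Krt8 2.86-fold (1.08 to 10.7), and S100a1 was 3.73-fold lower (2.58 to 5.31).

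By the size rule for named genes, the largest ratios toward inner medulla were those of S100a6, a calcium-binding protein gene, with 561 UMIs against 0 (at least 24.6-fold), and of Muc1 (at least 9.55-fold), a membrane mucin gene. Aldh1a3, a retinoic acid-forming enzyme gene (at least 8.98-fold), Nupr1 (at least 8.94-fold), Rnf183 (at least 7.41-fold), Foxq1 (at least 5.26-fold), Hsd17b11 (at least 5.17-fold), Tmem158 and Tspan6 (114 UMIs each) were also without a UMI in cortex. Plet1 had 1140 UMIs against 3, with an interval of the ratio from 17.1 to 243. Toward cortex, Car15, a membrane carbonic anhydrase gene, had 3 against 89 UMIs, a ratio of 226 (74.8 to 1115), and the calcium-binding protein genes Calb1 and S100g had ratios of 164 (42.6 to 1393) and 82.7 (40.2 to 198). Both are also markers of connecting tubule cells, and S100g stood at 3005 CPM over all other cells of the cortex library. Klk1, another such marker, stood at 175 CPM in principal cell-like and 82963 CPM in connecting tubule-like cells of cortex. Ccnd1 was 35.9-fold lower (15.6 to 96.0), Defb1 16.5-fold (12.1 to 22.7), Ndrg1 17.9-fold (9.92 to 33.7), Tmem213 13.1-fold (7.57 to 23.3), Ldhb 8.27-fold (6.27 to 10.9), Car2 7.80-fold (5.99 to 10.2) and Lgals3 6.15-fold (4.23 to 8.91). Among class markers, the transcription factor gene Elf5 had 170 against 2 UMIs, a ratio of 11.2 (3.05 to 93.0), Kcne1 had 0 against 19 UMIs, and Avpr2, the vasopressin receptor gene, differed little, at 642 against 673 CPM.

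After thinning to a common total, a median of 1939.5 genes differed by 1 or more on the log2 scale among 3510 at 100 CPM or above, against 1427.5 between the whole kidney libraries and 1281 from counting noise alone. At 500 CPM or above the numbers were 201.5, 47.5 and 24. Principal cell-like cells of inner medulla lay mostly in cluster 8 (448 of 486) and those of cortex in cluster 9 (56 of 56). Cluster 8 was led by Aqp4, Plet1, S100a6, Aldh1a3 and Cryab and cluster 9 by Hsd11b2, Aqp3, Car15 and Lgals3, so these genes also drew the clusters, and a cluster of mainly 1 library could be that library rather than a cell type. Kap, an androgen-regulated proximal tubule gene taken as a sign of free RNA, stood at 236 CPM in these cells of inner medulla and 4562 CPM in those of cortex.

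**Figure D2:**
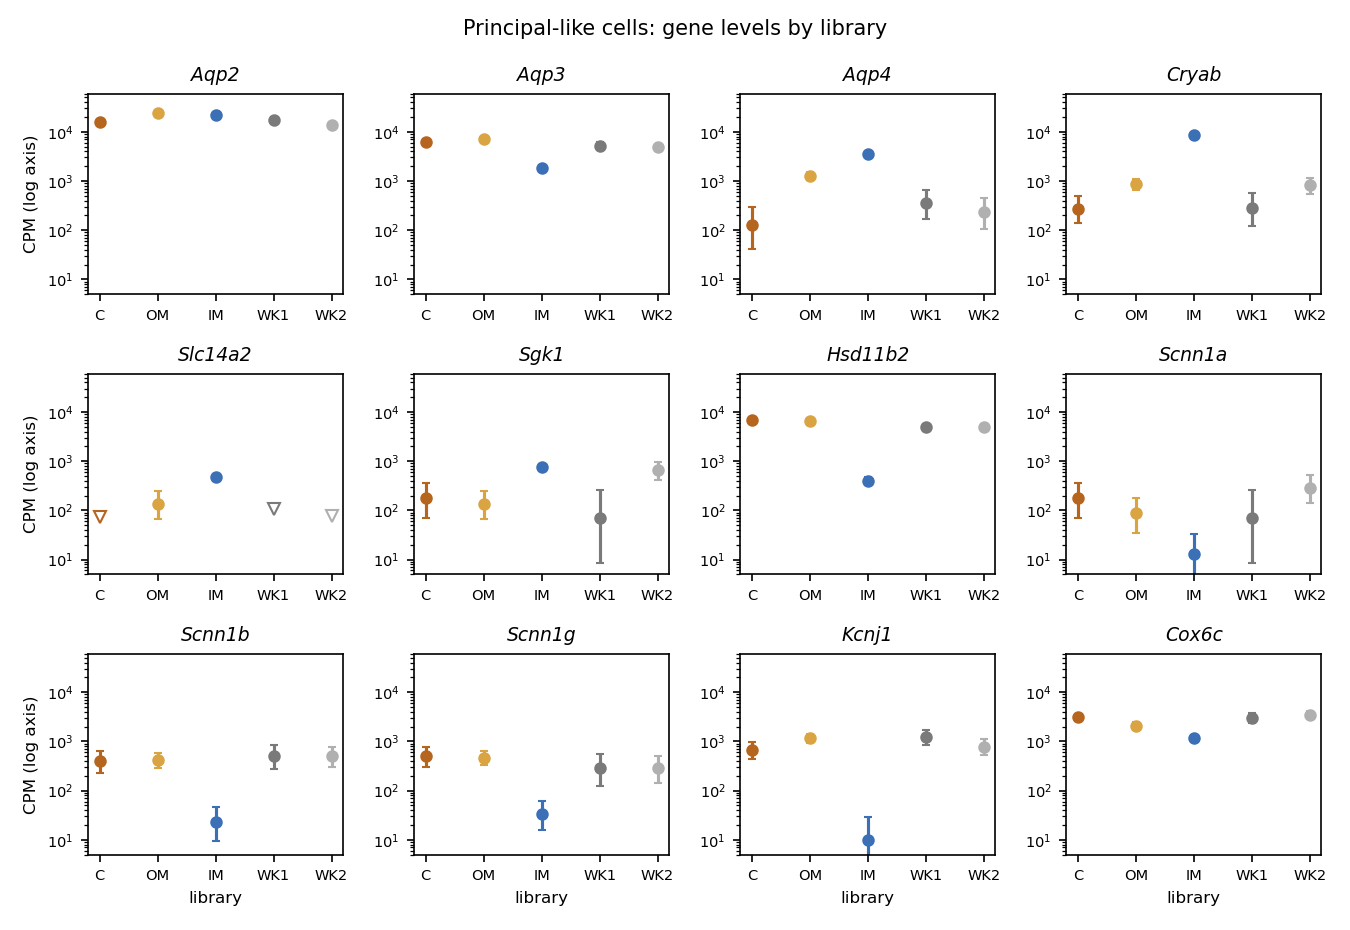
Level of 12 genes in principal cell-like cells (y axis, CPM on a log axis) in the libraries of cortex (C), outer medulla (OM), inner medulla (IM) and whole kidney (WK1, WK2), with exact 95% Poisson intervals, some of which run below the axis; open triangles mark the level that 3 counts would give where 0 UMIs were seen. Aqp4 stands at 1282 CPM in outer medulla and 3544 CPM in inner medulla, while Hsd11b2 is at 6731, 6447 and 393 CPM.

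In the outer medulla (162 cells, 80353 UMIs), principal cell-like cells stood nearer to those of cortex. The outer medulla library also held podocyte-like cells (0.620%, against 0.782% in cortex) and distal convoluted tubule-like cells (4.51%, against 6.48%). These shares, not far below those of cortex, point to cortical tissue in that library. Its amount was not measured, and it could lessen the differences between outer medulla and cortex given below. Values close between the 2 libraries therefore do not show that the regions are alike. Aqp4 was already higher, at 1282 CPM or 10.3-fold (4.27 to 32.3), and Slc14a2 had 11 UMIs against 0, at least 1.83-fold higher. Plet1 had a ratio of 5.99 (1.89 to 30.4) and Cryab was 3.13-fold higher (1.65 to 6.56), although Cryab also differed by 1.48 on the log2 scale between the whole kidney libraries. Fxyd4 was 2.19-fold higher (1.90 to 2.53) and Aqp2 stood at 24156 against 16156 CPM (interval 1.37 to 1.64). S100g was 9.68-fold lower (5.78 to 17.1) and Calb1 2.69-fold lower (1.66 to 4.40), both also markers of connecting tubule cells, and Car15 was 2.03-fold lower (1.49 to 2.75).

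The sodium channel genes did not follow the inner medulla pattern. Scnn1b stood at 423 against 399 CPM, Scnn1g at 460 against 499 CPM and Hsd11b2 at 6447 against 6731 CPM, all with intervals that included equality. The median of the sodium and potassium list was -0.09 at the 60.4 percentile and turned to 0.13 with TMM factors, with 2 of 14 members higher and 1 lower by interval. Kcnj1 was 1.74-fold higher (1.12 to 2.77). The osmolyte list had a median of -0.34 at the 25.9 percentile (-0.16 with TMM factors) and the water and urea list 0.45 at the 91.8 percentile, with Aqp3 at 7143 against 6258 CPM. Of the oxidative phosphorylation genes, 19 of 24 were lower and 9 by interval, with a median of -0.37 at the 1.78 percentile, and 15 of 24 were lower with TMM factors, at a median of -0.15.

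Further genes past the size rule toward outer medulla were Neat1, a nuclear long non-coding RNA (6.09-fold, 2.47 to 19.4), Hnrnpab (3.64-fold, 1.64 to 9.50), H3f3b (2.75-fold, 1.65 to 4.82), Pcbp1 (4.37-fold, 1.56 to 16.9), Ube2b (3.19-fold, 1.24 to 10.5), Psmb3 (2.83-fold, 1.17 to 8.24), Gipc2 (2.75-fold, 1.14 to 8.02) and Snx6 (2.66-fold, 1.10 to 7.79). Sod2 (2.62-fold, 1.53 to 4.55) and Uqcr10 (2.44-fold, 1.71 to 3.51) were lower. Thinned sums gave 1482.5 genes past the size, close to 1427.5 between the whole kidney libraries and 1258 from counting noise, and 66.5, 47.5 and 23.5 at 500 CPM or above. At this depth most single genes with few UMIs cannot be set apart from the library spread.

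Thick ascending limb-like cells, which take up salt without water, were compared between outer medulla (231 cells, 98694 UMIs) and cortex (66 cells, 32954 UMIs). Umod, the uromodulin gene, and Slc12a1, the sodium-potassium-chloride cotransporter gene, were close, at 11004 against 12836 CPM and 7599 against 6494 CPM. Cldn10, a cation-pore claudin gene, was 2.13-fold higher in outer medulla (1.55 to 2.97), as were Kcnj1 (2.23-fold, 1.21 to 4.49) and Fxyd2 (2.04-fold, 1.76 to 2.36). Ptger3, a prostaglandin E2 receptor gene, was 4.06-fold higher (1.78 to 11.4). Pth1r, the parathyroid hormone receptor gene, was 5.03-fold lower, at 253 against 1275 CPM, and Casr, the calcium-sensing receptor gene, 2.72-fold lower (1.04 to 7.06).

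The divalent cation list had a median log2 ratio of -0.65 at the 1.55 percentile, with 6 of 6 members lower and 2 by interval, but it differed by -0.54 between the whole kidney libraries. With TMM factors (shift -0.28), its median was -0.38 and 4 of 6 were lower. Cldn16 and Cldn19, the claudins of the paracellular calcium and magnesium path, stood at 324 against 455 CPM and 415 against 425 CPM. The salt transport list had a median of 0.19 at the 75.2 percentile, 0.48 with TMM factors and 0.08 with zero-count genes at their bound, with 4 of 10 members higher by interval. The macula densa list had 3 measured members, all lower and none by interval. The osmolyte list had a median of 0.59 at the 74.2 percentile, or 0.00 with zero-count genes at their bound.

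Among genes past the size rule, Egf, a growth factor gene of the distal nephron, was 2.24-fold lower in outer medulla (1.88 to 2.67), Klk1 3.03-fold (2.55 to 3.60), Car15 4.26-fold (527 against 2246 CPM), Sfrp1 3.10-fold (2.13 to 4.51) and Tmem52b 5.60-fold (3.30 to 9.73). Sfrp1 and Tmem52b were also among the leading genes of the distal convoluted tubule-like cluster, whose markers Slc12a3 and Pvalb had 0 and 2 UMIs in these cells of cortex. Klk1 is a marker of connecting tubule cells, and its level over all other cells of the cortex library was 4726 CPM against 8193 CPM in this class. Cryab had 31 UMIs against 1, a ratio of 10.4 (1.73 to 422), Cox20 50 against 2, a ratio of 8.35 (2.19 to 70.8), and Nccrp1 37 against 3, a ratio of 4.12 (1.30 to 20.9). Ccnd1 was 3.84-fold higher (1.68 to 10.8), and Slc16a7 (3.42-fold, 1.24 to 13.2), Iah1 (3.17-fold, 57 against 6 UMIs) and Ube2b (3.01-fold, 1.20 to 9.70) were higher as well, while B3gnt2, Gadd45g, Tmem70 and Tmem86a each rested on 3 UMIs in cortex. Thinned sums gave 1075.5 genes past the size, against 1092 between the whole kidney libraries and 959 from counting noise. With the class taken from each cell's own marker score, Fxyd2 and Kcnj1 lost their excess, at log2 ratios of -0.01 and -0.21.

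Proximal tubule-like cells gave the deepest comparison, with 1597 cells and 1303481 UMIs in outer medulla and 2313 cells and 2052013 UMIs in cortex. Only 3 genes passed the size rule. Ttr, the transthyretin gene, was 3.77-fold higher in outer medulla (3.58 to 3.96), at 3925 against 1042 CPM, Ppic, a cyclophilin gene, 2.45-fold higher (1.87 to 3.22), and Mir692-1 2.33-fold lower (2.03 to 2.68). Cyp7b1, a hydroxylase gene of the late proximal tubule that lies below the level required of named genes, had 46 UMIs in outer medulla and 2 in cortex, a ratio of 36.2 (9.47 to 308).

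Genes of the early proximal segments S1 and S2 were slightly lower in outer medulla in 9 of 10 cases, 6 by interval, with a median log2 ratio of -0.22 at the 0.84 percentile, against 0.12 between the whole kidney libraries. Slc34a1, the phosphate cotransporter gene, was 1.27-fold lower (1.21 to 1.32), Slc5a12, a lactate transporter gene, 1.44-fold (1.31 to 1.59) and Slc22a8, an organic anion transporter gene, 1.60-fold (1.39 to 1.84), while Slc34a3 was 1.33-fold higher (1.03 to 1.71). Segment S3 genes had a median of 0.02 at the 60.4 percentile, with 2 of 7 higher by interval, Slc7a13 at 1.25-fold (1.13 to 1.37) being the other beside Cyp7b1, and Slc6a18 1.48-fold lower (1.10 to 2.01). Among class markers, Napsa was 1.73-fold higher (1.61 to 1.87) and Kap 1.49-fold (1.48 to 1.51), and Ass1, of arginine synthesis, was 1.57-fold lower, at 1916 against 3013 CPM. Lrp2 and Pck1 were 1.43-fold (1.31 to 1.56) and 1.41-fold (1.29 to 1.55) lower. Between the whole kidney libraries, 95% of proximal genes with at least 100 UMIs differed by 0.49 or less on the log2 scale. In value, Ttr, Ppic, Mir692-1, Napsa, Kap, Slc22a8, Slc5a12, Ass1 and Lrp2 lay beyond that limit and Slc34a1 and Pck1 did not. The intervals of Slc22a8, Slc5a12 and Lrp2 reached below the limit, and that of Pck1 reached above it. As a percentile of a single pair, the limit is passed by some genes between libraries of the same kind by definition. Thinned sums gave 11 genes past the size, against 6 between the whole kidney libraries and 0 from counting noise.

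Intercalated cell-like cells of outer medulla (53 cells, 27609 UMIs) were compared with those of cortex (71 cells, 44987 UMIs). Aqp6, a vesicular water channel gene of acid-secreting alpha cells, was 2.44-fold higher in outer medulla (1.51 to 4.02), at 1630 against 667 CPM, and Dmrt2, a transcription factor gene of alpha cells, had 12 against 6 UMIs, a ratio of 3.26 (1.13 to 10.6). The anion exchanger gene Slc4a1 stood at 471 against 356 CPM, Kit at 3 against 7 UMIs and Adgrf5 at 507 against 400 CPM, with intervals that included equality. All 4 genes of bicarbonate-secreting beta cells were lower in value, Slc26a4, the pendrin gene, at 869 against 1245 CPM and Slc4a9 at 435 against 778 CPM, and none by interval. The alpha list had a median of 0.40 at the 86.0 percentile, with 2 of 5 members higher by interval, but it differed by more, -0.75, between the whole kidney libraries, and TMM factors moved it to 0.19. The beta list had a median of -0.61 at the 3.72 percentile, or -0.82 with TMM factors, against 0.03 between the whole kidney libraries.

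The proton pump subunit genes that mark the class were close, Atp6v1g3 at 9309 against 11759 CPM and Atp6v0d2 at 2028 against 1600 CPM. Past the size rule, Ly6e was 7.06-fold higher in outer medulla (3.36 to 16.6), Tmsb4x 5.39-fold (2.84 to 10.9), Serpinb9 2.60-fold (1.64 to 4.18) and Epcam 2.34-fold (1.43 to 3.86). Ly6e also differed by -2.31 on the log2 scale between the whole kidney libraries. Lamp1 was 3.24-fold lower (1.68 to 6.84), Eef2 2.84-fold (1.30 to 7.06), Klk1 2.40-fold (1.84 to 3.17), Uqcr10 2.39-fold (1.58 to 3.73), Ppia 2.21-fold (1.33 to 3.83), Atp5g1 2.19-fold (1.43 to 3.46), Naca 2.18-fold (9 against 32 UMIs) and Etfa 2.03-fold (1.21 to 3.53). Thinned sums gave 1384.5 genes past the size, against 1323 between the whole kidney libraries and 1165.5 from counting noise.

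**Figure D3:**
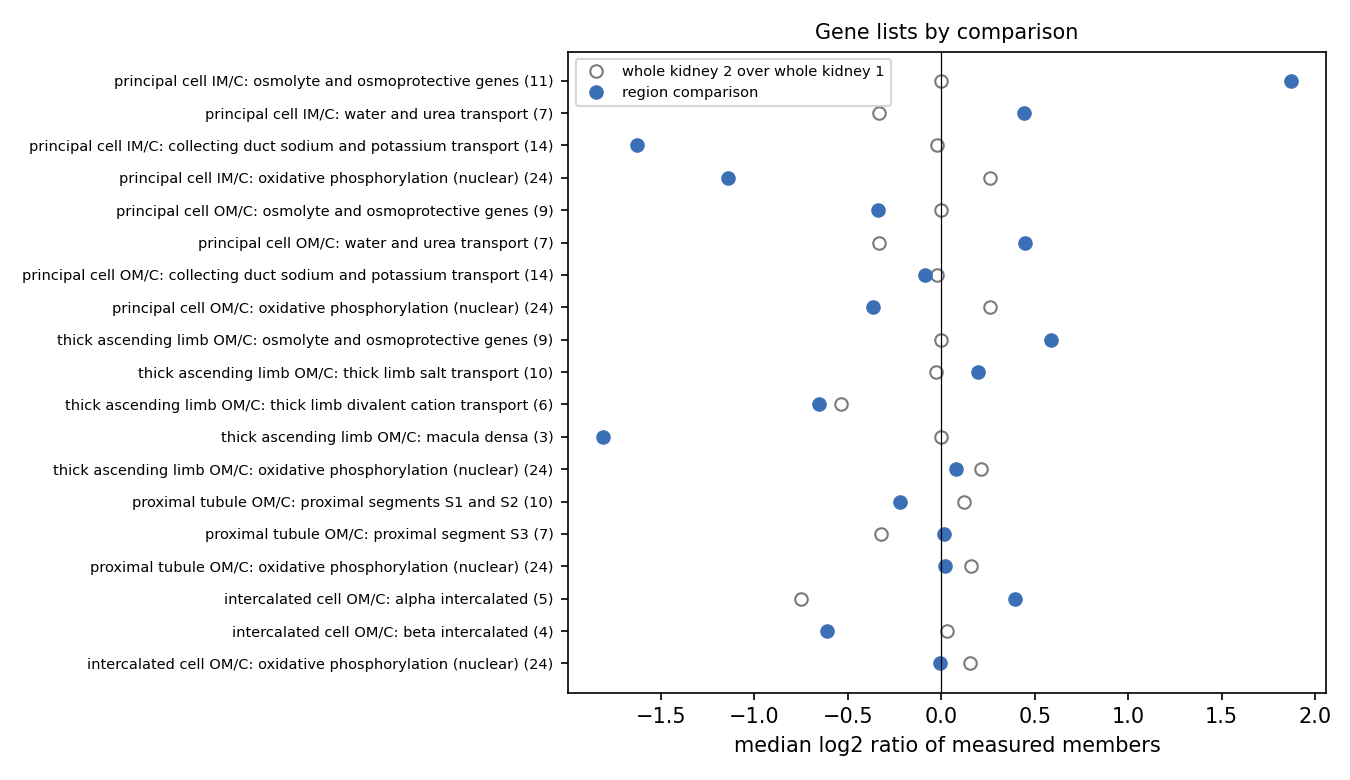
Median log2 ratio (x axis) of the measured members of each gene list (y axis, number of members in parentheses) in the outer medulla over cortex (OM/C) and inner medulla over cortex (IM/C) comparisons (filled points), with the same lists between whole kidney 2 and whole kidney 1 (open points). In principal cell-like cells of inner medulla, the sodium and potassium list (-1.63) lies far from its whole kidney value (-0.02); the osmolyte list (1.87) is at 0.66 with zero-count genes at their bound.

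Thin limb-like cells were not compared between inner and outer medulla, nor endothelial-like cells between inner medulla and cortex, because the outer medulla held 24 thin limb-like cells with 9841 UMIs and the inner medulla 34 endothelial-like cells with 14253 UMIs. A class needed 30 cells and 20000 UMIs, and the endothelial-like cells fell short in UMIs only. With the class from each cell's own marker score, both met these limits (185 and 114 cells, and 49 and 55 cells), with 1647.5 and 1686 genes past the size. No whole kidney or counting-noise count was made beside these 2 values, so they cannot be read as regional differences. The 2 whole kidney libraries, compared class by class, differed by a median of 0.15 on the log2 scale over 4540 genes of proximal tubule-like cells with at least 100 UMIs, 0.25 over 69 genes of principal cell-like cells, 0.23 over 42 genes of thick ascending limb-like cells and 0.23 over 102 genes of intercalated cell-like cells. The 95th percentiles were 0.49, 0.77, 0.78 and 0.63.

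The regional signature of principal cell-like cells was then looked at in the whole kidney libraries, whose cells carry no region label. The 50 genes with the largest ratios toward inner medulla, led by S100a6, Muc1 and Aldh1a3, took 31853 CPM of principal cell-like UMIs in inner medulla (31223 to 32492, exact Poisson) and 524 CPM in cortex (324 to 800), as they were chosen to. They took 5887 CPM (5368 to 6442) in outer medulla, 3694 CPM (3018 to 4476) in whole kidney 1 and 3719 CPM (3132 to 4383) in whole kidney 2. The 50 genes toward cortex, led by Car15, Calb1 and S100g, took 89629, 73600 and 21930 CPM in cortex, outer medulla and inner medulla, and 86986 and 88704 CPM in the whole kidney libraries.

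Across the whole kidney principal cell-like cells with at least 500 UMIs, thinned to 500, the correlation of inner medulla and cortex scores was -0.37 in whole kidney 1 (21 of 54 cells) and 0.02 in whole kidney 2 (23 of 61 cells). Among 1000 pairs of random lists matched on mean expression, these lay at the 6.30 and 57.5 percentiles, and the 95% range of random pairs was -0.46 to 0.45 and -0.42 to 0.40. A mean of 1.90 and 1.65 UMIs per cell came from the inner medulla list, and cells of a library are not independent replicates. With all cells thinned to 200 UMIs, added after seeing the data, the correlation in whole kidney 1 was -0.304 over 54 cells, just below its random range of -0.297 to 0.247, and that in whole kidney 2 was -0.14 over 61 cells, within its range of -0.28 to 0.26. Correlations below the random range were thus seen in whole kidney 1 under some settings and in whole kidney 2 under none of those run. Cluster 8, where most principal cell-like cells of inner medulla lay, held 3 of the 54 cells of whole kidney 1 and 1 of the 61 of whole kidney 2. With so few cells of that kind, the correlation cannot decide whether the signature orders cells by region.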

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

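All tests in this part were chosen after the result was seen.

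A group of 273 cells outside every comparison, left without a class, came from the cluster led by Cd74, H2-Aa, H2-Ab1, Lyz2 and Iigp1. It held 2.18% of cells in cortex, 5.21% in outer medulla, 0.446% in inner medulla, 1.62% in whole kidney 1 and 1.12% in whole kidney 2. Doublets with macrophage-like cells stay open: these cells had 0.0610 Lyz2 UMIs per Cd74 UMI against 0.566 in macrophage-like cells, but Lyz2 led the split between them. Free RNA stays open as well: Cd74 in outer medulla, at 2018 CPM, was 23.5 times its level in proximal tubule-like cells, but Cd74 is the gene that led the cluster. There was 1 outer medulla library, so the higher share there cannot be told apart from a property of that library.

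Endothelial-like cells of inner medulla, which entered no comparison, held Cryab at 27012 CPM (24381 to 29850, 385 UMIs), against 2 UMIs in those of cortex. Free RNA is argued against as the whole source, since the level was 3.15 times that of barcodes with under 100 genes (8585 CPM). Doublets would dilute the partner's level, yet it was 1.29 times that of thin limb-like cells (20897 CPM), and a subset of thin limb-like cells richer in Cryab was not excluded. A regional difference of the endothelium may remain, untested beyond this library.

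Proximal tubule-like cells of inner medulla, in no planned comparison, made up 10.2% of its cells, although the proximal tubule ends above that region. The share was 5.83% with cells of at least 500 genes and 5.13% with the class from each cell's own marker score. The values that follow are for the cells of the main setting. Proximal markers took 11.8% of their UMIs (11.5 to 12.1) against 1.65% in barcodes with under 100 genes. The same markers named these cells, so this difference cannot decide on free RNA, which stays open. Late segment S3 genes had a median log2 ratio of 0.66 over cortex and early segment genes -1.05, the directions that carry-over of outer medulla at the dissection border would give. The outer medulla library as a whole had medians of 0.02 and -0.22, so its proximal tubule-like cells on the whole differ from these. Cortical tissue in that library could lessen its medians, so the comparison cannot decide, and carry-over of outer medulla or of a deeper part of it stays open. No biological explanation was tested.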

How the results depend on the processing

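The level filter of 500 CPM, the removal of the 5% highest doublet scores, the subtraction of a free RNA profile and thinning to 200 UMIs were added after seeing the data, and the other alternatives were planned. No paired analysis was possible because the labels pair no libraries. Of the values of named genes under all alternatives, 3444 stayed within the counting interval of the main value, 94 moved and 2 reversed. That interval is wide for genes with few UMIs and open on a side for genes with 0 UMIs in a library, so staying within it is weak evidence. Of list medians 163 stayed and 36 moved, judged by the spread of 200 Poisson resamples. Of class shares 170 stayed and 66 moved, judged by their binomial interval. Those that stayed include the average principal cell-like share with either whole kidney library left out. That average was judged by the standard deviation of the 2 libraries and was bound to stay. The signature correlation averaged over the whole kidney libraries moved by no more than the standard deviation of their 2 values (0.27) in every alternative that gave it. That deviation exceeds the size of the average (-0.17), so a loss of the correlation would also count as unmoved. Leaving out 1 of the 2 libraries could not move the average past it. The correlation in whole kidney 1 alone did not stay at -0.37. It was -0.47 at Leiden resolution 0.5, -0.44 with up to 20 genes per list and -0.73 with at least 500 genes (12 cells), each below its range of random pairs, and 0.03 with the class from each cell's own marker score, within it. Thinning to 1000 UMIs left too few cells.

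Counts of genes past the size followed the level filter by construction. They are given in the order principal cell-like inner medulla, principal cell-like outer medulla, thick ascending limb-like, proximal tubule-like and intercalated cell-like, each against cortex. The last value is whole kidney 2 over whole kidney 1 in principal cell-like cells only, as are the other whole kidney counts here unless a class is named. Without a filter they were 5203, 4646.5, 4259.5, 33.5, 4452 and 4570.5, and at 500 CPM they were 201.5, 66.5, 70.0, 2, 74.5 and 47.5. At 500 CPM the whole kidney count was 74 in thick ascending limb-like, 2 in proximal tubule-like and 52 in intercalated cell-like cells. At 50 CPM the principal cell-like outer medulla, thick ascending limb-like, intercalated cell-like and whole kidney counts were 2257, 1785, 2118.5 and 2217.5. With the class from each cell's own marker score, the principal cell-like outer medulla, thick ascending limb-like and whole kidney counts were 926.5, 478 and 821, the principal cell-like share of inner medulla was 45.0%, and in thick ascending limb-like cells Fxyd2 and Kcnj1 reversed to log2 ratios of -0.0054 and -0.21. A mean over cells gave 1673 genes for thick ascending limb-like cells, a pseudocount of 50 CPM gave 6 for proximal tubule-like cells, and cells with at least 500 genes gave a principal cell-like share of 78.6%. The cause was not tested for the changes under the marker score, the mean over cells and the cells with at least 500 genes. With at least 500 genes, the principal, thick ascending limb, intercalated and whole kidney comparisons were not run, because too few cells or UMIs were left. The filter on the mitochondrial share was void. Depth in the cortex sums limits what can be seen toward cortex.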

Other observations

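The comparisons in this part were unplanned, were chosen after the data were seen and carry counting error only. Intercalated cell-like cells of inner medulla (40 cells, 21183 UMIs) held more of the genes of acid-secreting alpha cells than those of cortex and less of the beta cell genes. Aqp6 was 4.60-fold higher (2.94 to 7.35), at 3068 against 667 CPM, the anion exchanger gene Slc4a1 2.65-fold higher (1.31 to 5.48), Adgrf5 2.71-fold (1.40 to 5.34) and Dmrt2 3.54-fold (1.17 to 11.8). The pendrin gene Slc26a4 had 4 against 56 UMIs, 189 against 1245 CPM or 6.59-fold lower, Slc4a9 had 2 against 35 UMIs, a ratio of 8.24 (2.12 to 70.7), and Hmx2 3 against 35 UMIs, a ratio of 5.49 (1.73 to 27.9). The alpha list had a median log2 ratio of 1.42 (4 of 5 members higher by interval) and the beta list -2.79 (4 of 4 lower by interval; -2.52 with zero-count genes at their bound), against -0.75 and 0.03 between the whole kidney libraries. Free RNA was estimated at 25.1% of UMIs in these cells of inner medulla and 17.6% in those of cortex.

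Thick ascending limb-like cells of inner medulla (107 cells, 67718 UMIs) differed from those of outer medulla in genes of divalent cation transport, with 6 of 6 lower and 4 by interval, at a median log2 ratio of -1.48, against -0.54 between the whole kidney libraries. Free RNA was estimated at 4.38% of UMIs in these cells and 19.9% in those of outer medulla, and genes of proximal segments S1 and S2 moved with it, at a median of -3.10 or of -1.18 with zero-count genes at their bound. The claudin gene Cldn16 had 2 against 32 UMIs, with an interval of the ratio from 2.80 to 94.5, and Cldn19 13 against 41 UMIs, 2.16-fold lower (1.14 to 4.40). Egf was 4.42-fold lower (3.24 to 6.15), at 694 against 3070 CPM, Umod 1.91-fold lower (1.70 to 2.14) and Slc12a1 1.53-fold lower (1.34 to 1.74), while Cldn10 was 1.25-fold higher (1.05 to 1.49) and Ppp1r1a 1.28-fold higher (1.11 to 1.48). The salt transport list was balanced, with 5 members higher and 5 lower. Nuclear oxidative phosphorylation genes were higher in 21 of 24 cases, 17 by interval, and 0 were lower by interval. Their median was 0.41, against 0.21 between the whole kidney libraries. The thick ascending limb-like cells of inner medulla lay in the same cluster as those of the other libraries. Carry-over of outer medulla, considered above for proximal tubule-like cells of this library, was not tested for them. The differences therefore cannot be assigned to the inner medulla as a region.

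Cryab stood at 20897 CPM in thin limb-like and 8756 CPM in principal cell-like cells of inner medulla, and at 8585 CPM in that library's barcodes with under 100 genes. In proximal tubule-like cells of inner medulla, Napsa was 5.03-fold higher than in those of cortex (4.29 to 5.86) and Slc5a2, the sodium-glucose cotransporter gene of the early segments, 3.23-fold lower (1.69 to 7.07). Among 167 genes of the fixed lists in the planned comparisons of outer medulla with cortex, 29 passed the size with their interval in a class, and 0 of these did so in the opposite direction in another class.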
